A study of Xenopus laevis with 6 samples.

How the data were processed

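Liver libraries of 3 control tadpole samples and 3 samples exposed to 4.4 µg/L atorvastatin were compared, with groups and replicate numbers taken from the sample titles. RNA was extracted with a spin-column kit, per the labels' protocols; the aligner, the counting software and its version, the library type and the use of strand are not given in the sources used here. Each deposited table lists 72899 RefSeq transcripts of 34462 genes for 1 library. Per the file headers, the authors' tables hold counts of total and of unique reads per transcript, as whole numbers, and each total is the unique reads plus reads shared between transcripts that were assigned to that transcript. The deposited TPM and RPKM values were computed by the authors from these reads and the transcript lengths; within a file, RPKM times length over total reads is a constant, whose denominator exceeds the sum of transcript reads. TPM was used only for an alternative and RPKM only for that check. In each file 1 line held no values and was not used here. How reads shared between near-identical L and S copies or between members of a gene family were divided is not given, so that values of such genes are uncertain, as are those of overlapping genes on opposite strands.

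All 34462 gene IDs and symbols matched a RefSeq gene table of Xenopus_laevis_v10.1, and 98.8% of genes had the identical span there; coordinates are those of the deposited files. Total reads were summed per gene. The libraries held 52367582 to 65384908 such reads, of which 65.5 to 71.8% were unique to a transcript. At this depth 3 counts over the exposed group correspond to 0.0187 CPM, and this floor covers counting error only. The 10 most abundant genes took 24.0 to 35.2% of reads. No 2 libraries were duplicates, as the correlation of log2 CPM between libraries was between 0.918 and 0.966.

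The main test, fixed before the data were examined, was edgeR's quasi-likelihood F test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3) with group as the sole term, TMM factors and the filterByExpr filter, which kept 22129 genes. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The TMM factors were 1.133, 1.071 and 1.391 for the controls and 0.741, 0.852 and 0.938 for the exposed libraries. The SE was the fold change divided by the square root of the F statistic. The biological coefficient of variation was 0.44. The 29 gene lists, covering the drug's pathway, liver functions, stress and other cell types, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Members were also adjusted over their list alone. The named genes were chosen by a rule fixed in advance: ldlr; up to 8 genes per direction of largest fold change among those past the threshold with separate groups, a mean of at least 1 CPM and a symbol that is not a placeholder, filled up to 5 per direction by the smallest p; and up to 4 members of smallest p of each list described. Some genes that the rule takes are not reported here.

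Alternatives were DESeq2 1.42.0, other size factors, library size alone, no filter or a stricter filter on low counts, the replicate number as a block, unique reads, transcripts in place of genes, summed L and S copies, limma-trend on log2 of TPM with pseudocounts of 1 and 0.1, limma-voom with quality weights, and each replicate left out in turn. Removal of globin genes, and list tests with library size alone or with the block and an estimated correlation, were added after the data were seen. The test was checked on simulated counts for this comparison (21558 genes tested) with the means, depths and dispersions of these libraries. Of 100 genes changed 2-fold edgeR recovered 1% and of 100 changed 4-fold 54%, with 9 false calls. DESeq2 recovered 10% and 90%, with 57 false calls. Only these 200 genes were changed, while the estimated share of unchanged genes in the real data was 76.9%. Recovery and false calls depend on that share, so these figures need not carry over to the real comparison. Of 200 lists of 40 unchanged simulated genes, 4 had an unadjusted camera p under 0.05. The genes were simulated independently of each other, so this check does not cover lists whose genes move together. In the real lists the estimated correlation reached 0.786 (ribosomal proteins). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.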

Results

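Liver RNA was sequenced from metamorphosing tadpoles of the African clawed frog, Xenopus laevis, kept as controls or exposed to atorvastatin dissolved in the water at 4.4 µg/L. Atorvastatin is a statin, a drug that lowers cholesterol synthesis. There were 3 control and 3 exposed libraries, and the series asks how a concentration of environmental relevance affects this species. Control replicates 1, 2 and 3 held 62867434, 52367582 and 65384908 reads assigned to transcripts, and atorvastatin replicates 1, 2 and 3 held 64886875, 61577888 and 64132130. The labels do not say whether the replicates of a group were separate animals, pools or tanks, so the p-values measure only the spread between these libraries, which may be technical in part. Xenopus laevis is an allotetraploid, and many genes have an L and an S copy, named by the suffix of the symbol. The suffix does not always match the chromosome given for the gene, as ahsg.L lies on 9_10S and cyp2c8.2.L on 8S. Means are in CPM, read counts scaled to a common library size with TMM factors, given ± SD with n = 3 per group, and fold changes are exposed over control on the log2 scale with their standard error (SE).

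Exposed livers held more transcript of a pair of autophagy genes and less of a tRNA synthetase gene. The S copy of map1lc3a, which encodes an LC3 protein of the autophagosome membrane, rose from 9.93 ± 1.94 to 51.9 ± 2.95 CPM (log2 fold change 2.38, SE 0.25, adjusted p = 0.0263). Its L copy did not pass, with 6.63 ± 1.92 and 10.7 ± 3.62 CPM and overlapping groups (log2 fold change 0.68, SE 0.35, edgeR adjusted p = 0.383). The S copy of gabarapl2, of the same protein family, rose from 5.80 ± 0.751 to 21.1 ± 1.90 CPM (log2 fold change 1.86, SE 0.23, adjusted p = 0.0496). The S copy of vars1, the valyl-tRNA synthetase gene, fell from 20.03 ± 3.99 to 4.85 ± 0.0116 CPM (log2 fold change -2.05, SE 0.24, adjusted p = 0.0496). In all, 12 of 22129 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 10 of them higher and 2 lower in exposed liver. In each of the 12 the 3 exposed libraries lay entirely on one side of the 3 control libraries. At an unadjusted p under 0.05 there were 3456 genes, or 15.6% of those tested against 5% with no difference, 1776 of them higher and 1680 lower.

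The other named genes that rose were of mixed function. The L copy of lyar, which encodes a nucleolar protein, rose from 0.431 ± 0.119 CPM in controls to 114 ± 95.5 CPM in exposed liver (log2 fold change 8.02, SE 0.86, adjusted p = 0.0263). The L copy of tmem86a, a lysoplasmalogenase gene, rose from 2.57 ± 0.232 to 14.9 ± 2.46 CPM (log2 fold change 2.54, SE 0.25). The remaining named genes were tm4sf20.L (log2 fold change 2.87, SE 0.35), hsd11b1l.2.S (2.20, SE 0.27) and XB5815362.S (2.52, SE 0.31). On Xenopus laevis v10.1, map1lc3a.S lies on chromosome 9_10S from 35803491 to 35816919, gabarapl2.S on 4S from 45946692 to 45954171, vars1.S on 8S from 82019545 to 82048834, and lyar.L on 1L from 27501347 to 27522017. All are annotated as protein-coding genes.

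Among the 12 genes were 4 with placeholder names, which lay outside the rule for named genes and were singled out after their values were seen. LOC121397773, on 8S from 81786050 to 81818386, rose from 189 ± 11.4 to 1350 ± 83.8 CPM (log2 fold change 2.84, SE 0.29, adjusted p = 0.0263). LOC121396193 and LOC108697819 rose by log2 fold changes of 2.74 and 2.60. LOC108699348, on 8L from 117955740 to 117972018, had 964, 1120 and 1360 reads in the control libraries and 0 reads in each exposed library. Against a floor of 3 counts over the exposed group, which is 0.0187 CPM, its control mean of 16.2 ± 3.38 CPM was at least 865-fold higher (adjusted p = 0.00511).

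**Figure D1:**
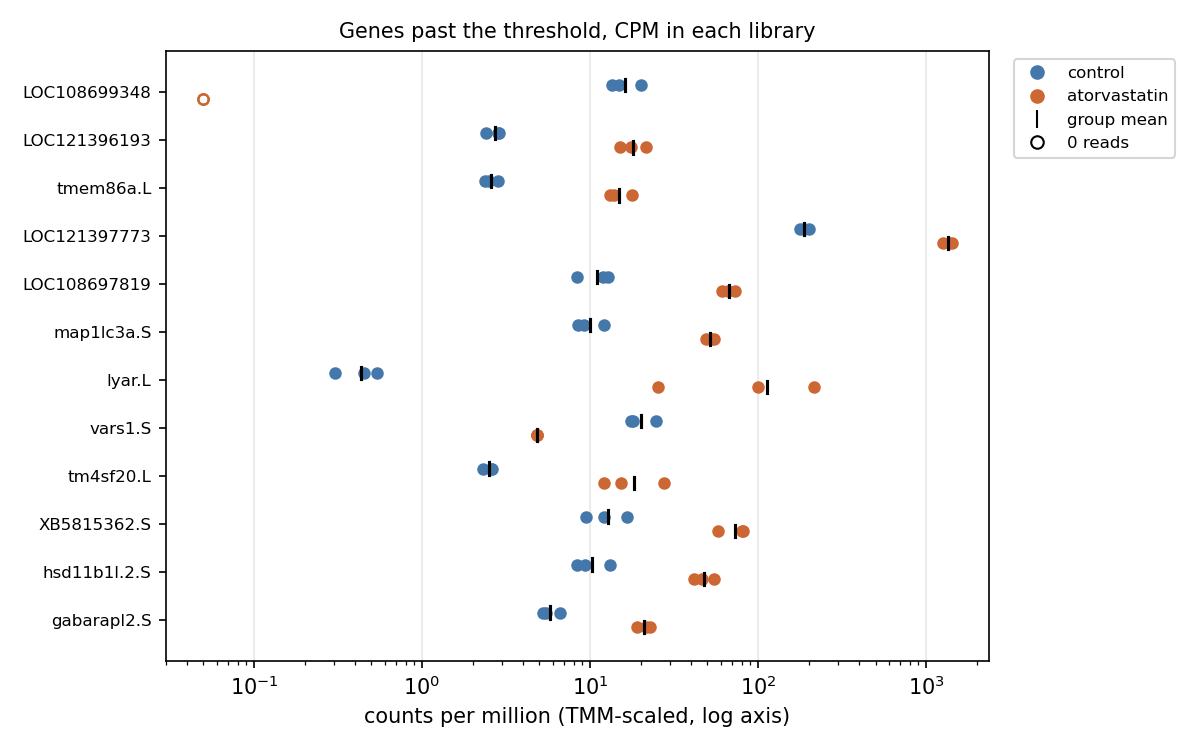
CPM (TMM-scaled, log axis) in each of the 3 control and 3 atorvastatin libraries for the 12 genes past an adjusted p of 0.05. Filled points are libraries, vertical bars are group means, and open circles, drawn at an arbitrary 0.05 CPM, are libraries with 0 reads; map1lc3a.S moved from a mean of 9.93 to 51.9 CPM.

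With 1 library left out, edgeR called 1, 0 and 0 genes without control replicate 1, 2 or 3, of which 1, 0 and 0 were among the 12, and 3, 3 and 6 genes without atorvastatin replicate 1, 2 or 3, of which 2, 1 and 4 were. At an unadjusted p under 0.05 there were 3368 genes without control replicate 2 and 2915 without control replicate 3. DESeq2 called 1264 genes on the same counts, 720 higher and 544 lower, including all 12, and with library size alone 559 genes passed, 30 higher and 529 lower, with the median of all tested genes at -0.53. Erythroid genes took 8.31 to 18.5% of reads in exposed libraries and 3.22 to 6.30% in controls, beside every gene group described here.

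Lower genes that came closest to the threshold without passing it were dnajc3.L (log2 fold change -2.23, SE 0.29, adjusted p = 0.0545), which encodes a co-chaperone of the endoplasmic reticulum (ER), tor3a.L (-2.65, SE 0.36, adjusted p = 0.0594), pla2g4f.L (-6.27, SE 0.86, adjusted p = 0.0594) and ttpal.S (-2.17, SE 0.30, adjusted p = 0.0594).

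The low-density lipoprotein receptor gene ldlr.L had 73.1 ± 27.2 CPM in controls and 22.9 ± 16.5 CPM in exposed liver (log2 fold change -1.68, SE 0.59, adjusted p = 0.229), and ldlr.S had a log2 fold change of -0.69 (SE 0.67, adjusted p = 0.657), so that neither copy passed.

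Of the 35 tested genes of cholesterol synthesis, the primary list, 29 had negative and 6 positive fold changes, with a median log2 fold change of -0.64. In edgeR's quasi-likelihood test 0 passed over all genes tested and 0 adjusted over the list alone. The members of smallest p were lbr.L (log2 fold change -1.84, SE 0.40, edgeR adjusted p = 0.0521 adjusted over the list alone), fdps.L (-1.25), ebp.L (-1.72) and nsdhl.L (-1.07). The camera test with its preset correlation placed the list below the other genes (adjusted p = 7.28e-06), and with an estimated correlation it did not (adjusted p = 0.813). The mean log2 level of the list relative to each gene's mean was 0.49, -0.02 and 0.92 in the 3 controls and 0.70, -0.60 and -1.48 in atorvastatin replicates 1, 2 and 3, so that the groups overlapped. The list median was -0.39 without control replicate 3, -1.62 without atorvastatin replicate 1 and -0.23 without atorvastatin replicate 3, where the preset test gave an adjusted p of 0.0538. With library size alone it was -1.35, or -0.81 relative to all tested genes.

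Of the 46 tested genes of the ER stress list, which holds chaperones, folding enzymes and regulators of the unfolded protein response, 20 fell and 0 rose adjusted over the list alone, while 0 passed over all genes tested. They included pdia4.L, a protein disulfide isomerase gene (166 ± 40.9 to 30.6 ± 12.4 CPM, log2 fold change -2.44, SE 0.37), hsp90b1.S, which encodes the chaperone GRP94 (154 ± 13.6 to 27.8 ± 14.7 CPM, -2.47, SE 0.40), canx.S, the calnexin gene (33.1 ± 4.39 to 12.1 ± 1.92 CPM, -1.45, SE 0.24), and dnajc3.L. Over the whole list the median was -0.71. With 1 library left out it ran from -0.55 without control replicate 1 to -1.19 without atorvastatin replicate 3. With library size alone it was -1.21, or -0.68 relative to all tested genes. The mean log2 level of the list relative to each gene's mean was 0.77, 0.52 and 0.25 in the controls. In atorvastatin replicates 1, 2 and 3 it was -0.57, -0.99 and 0.02. Of the 46 genes, 41 had negative fold changes. In 23 the exposed libraries lay entirely below the controls, where chance gives 10% for both directions together, 22.7% of all tested genes had separate groups, and other splits of the 6 libraries gave at most 11 list members in one direction. The preset camera test gave an adjusted p of 5.19e-16, and with an estimated correlation the p was 0.0766 (adjusted p = 0.813).

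**Figure D2:**
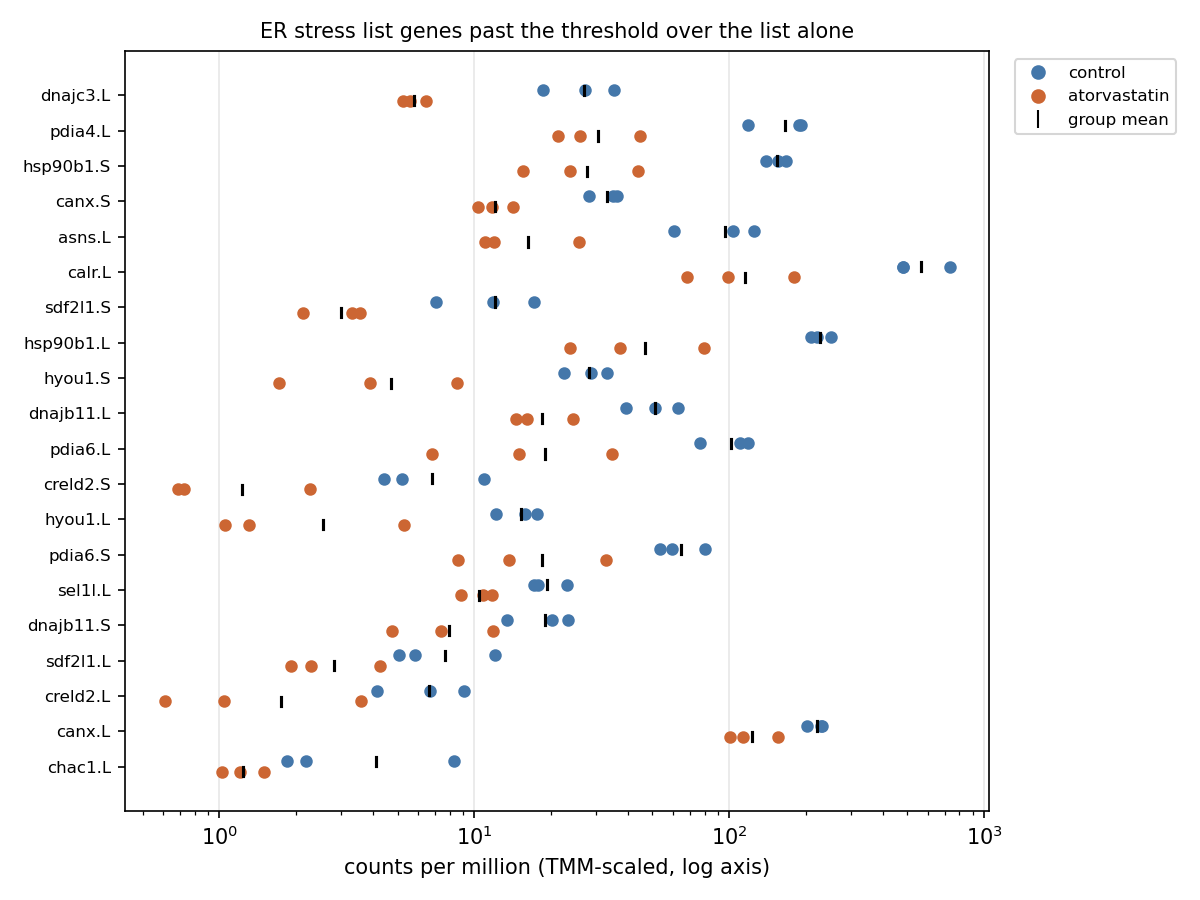
CPM (TMM-scaled, log axis) in each library for the 20 ER stress list genes that passed adjusted over the list alone. Points are the 3 control and 3 atorvastatin libraries and vertical bars the group means; hsp90b1.S moved from a mean of 154 to 27.8 CPM.

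In the list of glucose metabolism and insulin-like growth factor signalling, 14 of 47 tested genes rose and 3 fell adjusted over the list alone, and 0 passed over all genes tested. Those that rose included pck2.L, a gluconeogenic carboxykinase gene (87.9 ± 24.0 to 403 ± 53.9 CPM, log2 fold change 2.20, SE 0.32), g6pc1.2.S, a glucose-6-phosphatase gene (0.928 ± 0.159 to 26.0 ± 19.8 CPM, 4.81, SE 0.76), igf2.L (2.59, SE 0.50) and igfbp4.S (1.53, SE 0.31). The preset camera adjusted p was 4.46e-06 and the p with an estimated correlation was 0.0267 (adjusted p = 0.775). Without control replicate 1 the count adjusted over the list alone was 11, and with library size alone it was 10. With library size alone the list median of 0.50 became 0.00, which was 0.53 above the median of all tested genes.

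Genes of hepatocyte identity had mostly positive fold changes (35 of 43, median 0.59). Adjusted over the list alone 3 rose, namely serpinc1.S, f9.L and ahsg.L, which encode the plasma proteins antithrombin, coagulation factor IX and fetuin-A, with log2 fold changes of 2.28, 1.30 and 1.41, and 0 passed over all genes tested. With library size alone the list median was 0.11, or 0.65 above that of all tested genes. The transcription factor gene cebpa.L had a log2 fold change of -1.33 and did not pass. The preset camera adjusted p was 3.77e-06, and the adjusted p with an estimated correlation was 0.813.

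Lipid and bile acid genes moved in both directions. In bile acid synthesis and transport, 3 of 24 genes rose and 2 fell adjusted over the list alone: cyp7a1.L, the rate-limiting enzyme of bile acid synthesis, fell from 86.3 ± 75.9 to 3.38 ± 3.59 CPM (log2 fold change -4.68, SE 0.97), hsd3b7.L fell (-1.88, SE 0.39), and cyp46a1.1.L and cyp46a1.3.L rose (1.96 and 1.08). In fatty acid and triglyceride synthesis, 2 of 29 rose and 3 fell; the fatty acid synthase gene fasn.L fell from 242 ± 116 to 18.4 ± 17.9 CPM (-3.72, SE 0.79) and acly.S fell (-1.31), while pnpla3.L and elovl2.L rose (1.49 and 1.81). In fatty acid oxidation and ketogenesis, 3 of 33 rose and 2 fell, among them both copies of angptl4, which encodes an inhibitor of lipoprotein lipase (angptl4.S 2.47, SE 0.32, and angptl4.L 1.68, SE 0.35), against fabp1.S (-4.01) and slc25a20.L (-1.29). In sterol sensing and uptake, 2 of 26 rose adjusted over the list alone, insig1.S (2.20, SE 0.48) and npc1l1.L (1.83, SE 0.46). In none of these lists did a member pass over all genes tested. The preset camera adjusted p was 0.0148 for fatty acid and triglyceride synthesis, lower, 0.53 without atorvastatin replicate 3 and 0.132 with L and S copies summed, and the adjusted p with an estimated correlation was 0.813. For the other lists of this paragraph it was 0.338 or higher with all libraries, and for fatty acid oxidation 0.0111 without control replicate 1 and 0.0114 without atorvastatin replicate 1.

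Lipoprotein and sterol efflux genes had a median log2 fold change of 0.54 (22 of 28 positive; preset camera adjusted p = 0.00119), with 0 past the threshold adjusted over the list alone; apoa5.L had 3.36 and apoc1.L 1.31. The median was 0.30 without control replicate 1 and 0.04 with library size alone, which was 0.57 above that of all tested genes, and the adjusted p with an estimated correlation was 0.813. In the non-sterol branches of the mevalonate pathway, 25 of 34 fold changes were negative (median -0.30, preset camera adjusted p = 0.0497) and 0 passed; without control replicate 2 or atorvastatin replicate 1, 2 or 3 the adjusted p was 0.28, 0.055, 0.128 and 0.0576, and the median without control replicate 2 was -0.09. The adjusted p was 0.0648 with a stricter filter, 0.114 with L and S copies summed, 0.0517 with globin genes removed and 0.813 with an estimated correlation.

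In xenobiotic metabolism, 1 of 65 genes rose and 2 fell adjusted over the list alone: the drug efflux pump gene abcb1.L rose (1.31, SE 0.30), and cyp2c8.2.L and the organic anion transporter gene slco1b3.L fell (-5.32 and -6.21). The list median was 0.33, or -0.24 with library size alone, which was 0.29 above that of all tested genes, and its preset camera adjusted p of 0.0287 became 0.284 without control replicate 1, where the median was 0.15, and 0.73 without atorvastatin replicate 1, where it was -0.09. The adjusted p with an estimated correlation was 0.813. In the list of oxidative and heat stress, 3 of 48 rose and 1 fell: mt4.L, a metallothionein gene (115 ± 45.9 to 1515 ± 1156 CPM, log2 fold change 3.72), hmox1.L (1.28) and sqstm1.L (1.07), against the mitochondrial chaperonin gene hspd1.S (-2.13); the list as a whole had a preset camera adjusted p of 0.439. In the list of urea cycle and nitrogen, glul.S, the glutamine synthetase gene, rose (3.21, SE 0.54) and slc25a15.2.L and gpt2.L fell (-1.44 and -1.85) adjusted over the list alone. Its preset camera adjusted p of 0.0478, lower, became 0.619 without control replicate 2, 0.252 without atorvastatin replicate 2, 0.199 without atorvastatin replicate 3 and 0.057 with a stricter filter, and the adjusted p with an estimated correlation was 0.813.

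Of 58 cell cycle genes 57 had negative fold changes (median -0.58; preset camera adjusted p = 3.56e-10), and 1, the replication licensing gene mcm2.L, fell adjusted over the list alone (-1.57, SE 0.31). The median was -0.95 without atorvastatin replicate 2 and -0.36 without atorvastatin replicate 3. Ribosomal protein genes had a median of 0.66, with 134 of 145 positive (preset camera adjusted p = 5.74e-16). In 97 the exposed libraries lay entirely above the controls and in 1 below them, yet 0 passed adjusted over the list alone. With library size alone the median was 0.20, which was 0.73 above that of all tested genes. Lists matched to them on transcript length and expression had a median of 0.51, with the middle 95% from 0.37 to 0.61. The matched lists were drawn from all tested genes, the ribosomal ones included. They cannot tell how far length and expression account for the shift. Oxidative phosphorylation genes had a median of -0.24 (60 of 74 negative; preset camera adjusted p = 0.0148), with 0 past the threshold, and without control replicate 2 or atorvastatin replicate 2 or 3 the adjusted p was 0.917, 0.124 and 0.302 and the median 0.04, -0.16 and -0.06; without atorvastatin replicate 1 the median was -0.49. For these 3 lists the adjusted p with an estimated correlation was 0.813, 0.813 and 0.877. No list of the 29 passed with an estimated correlation, where 14 had passed with the preset value, 7 higher and 7 lower.

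Beside lists of cell type and tissue markers, lists without a member past the threshold and with a preset camera adjusted p above 0.05 were those of thyroid hormone response (0.747), steroid hormones and vitellogenin (0.0652), acute phase and complement (0.475), apoptosis and p53 (0.495) and the circadian clock (0.475). In the list of thyroid hormone response, the median (-0.10) and the test lay in the negative direction and the mean (0.05) in the positive. The thyroid median was -0.30 without control replicate 2 and -0.002 without control replicate 3. The steroid list passed without control replicate 2 (0.0353) and without atorvastatin replicate 3 (0.00305), and the acute phase list without control replicate 1 (0.0218). The camera test asks for a shift in a single direction. In fry's test for change in either direction the adjusted p was 0.0167 for the circadian clock list. For the thyroid, steroid, acute phase and apoptosis lists it was 0.371, 0.129, 0.112 and 0.166. The circadian clock list was not alone in passing this fry test. Its adjusted p was 0.00245 for sterol sensing and uptake and for oxidative and heat stress. It was 0.00423 for the glucose and hepatocyte lists and 0.00998 for the ER stress list. For cholesterol synthesis, cell cycle and ribosomal proteins it was 0.258, 0.153 and 0.0863.

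**Figure D3:**
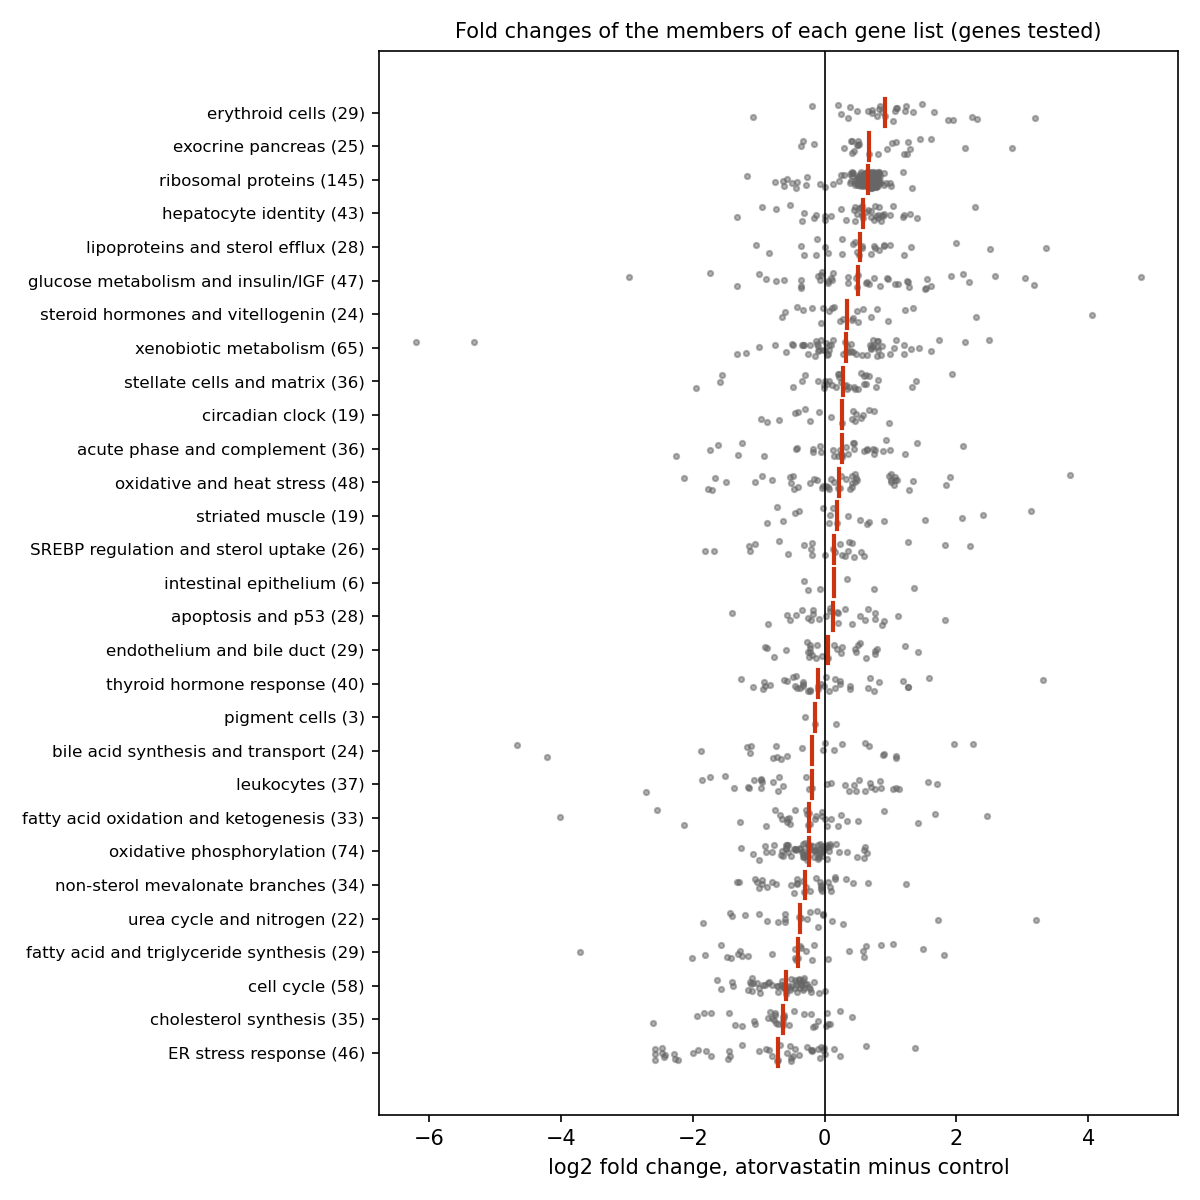
Log2 fold change (atorvastatin minus control) of each tested member of the 29 gene lists, with the number of genes tested in parentheses. Grey points are genes and red bars list medians; the ER stress list has the median of -0.71 and the erythroid list that of 0.91.

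Markers of other cell types and tissues differed between libraries. Of 29 erythroid genes, 27 had positive fold changes (median 0.91, or 0.33 without atorvastatin replicate 2), and 3 globin genes rose adjusted over the list alone, among them hba1.L and hbg1.L (log2 fold changes 1.94 and 1.87). The list took 3.22, 6.30 and 5.87% of reads in the controls and 8.38, 18.5 and 8.31% in the exposed libraries (preset camera adjusted p = 2.25e-06, 0.813 with an estimated correlation). Exocrine pancreas markers took 0.026% of reads in atorvastatin replicate 3 and between 0.002 and 0.012% elsewhere; the preset camera adjusted p of 0.0287, higher, became 0.735 without atorvastatin replicate 3 and 0.741 without control replicate 3, with the direction of the test turned in both; the list median was -1.34 without atorvastatin replicate 3 and stayed positive, at 0.36, without control replicate 3. It was 0.0771 with a stricter filter and 0.877 with an estimated correlation. Leukocyte markers took 0.83% of reads in control replicate 1 and between 0.146 and 0.243% elsewhere. Their median (-0.20) and mean (-0.18) were negative while the test lay in the positive direction (preset camera adjusted p = 0.508). Without control replicate 1 their median turned to 0.36 and the preset camera adjusted p was 0.0218. For the lists of intestinal epithelium, striated muscle, stellate cells and matrix, endothelium and bile duct, and pigment cells the adjusted p was 0.475, 0.223, 0.117, 0.475 and 0.862, with 0 members past the threshold in each. Leaving out atorvastatin replicate 3 brought the muscle and stellate lists to 0.0208 and 0.0115, and leaving out control replicate 3 the stellate and endothelium lists to 0.00172 and 0.0321.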

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

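The removal of globin genes, the list tests with library size alone or with the block and an estimated correlation, and the alternatives for the counts adjusted over the list alone were chosen after the data were seen. Against 12 genes in the main test, 1264 genes passed with DESeq2, 559 with library size alone, 138 without a filter, 122 with voom quality weights, 22 with globin genes removed, 5 on unique reads and 0 on transcripts in place of genes (2679 at an unadjusted p under 0.05, edgeR). On the log2 TPM scale limma-trend called 3341 genes with a pseudocount of 1 (78 higher and 3263 lower), 3424 with 0.1 and 1098 without a filter; these values carry no composition factor, and the median fold change was -0.52, -0.68 and -0.25. All 12 genes were shared with DESeq2, library size alone, no filter, voom and the globin-free counts. In simulated counts DESeq2 recovered 10 of 100 genes changed 2-fold and 90 of 100 changed 4-fold, with 57 false calls. For edgeR the numbers recovered were 1 and 54, with 9 false calls. The simulation had a smaller share of changed genes than estimated for the real data. It does not tell which of the 2 counts is nearer the truth. Leaving out 1 library gave between 0 and 6 genes; the cause was not tested. The 14 lists became 0 with an estimated correlation, with fry's test of a shift in a single direction, and with the block and an estimated correlation. With 1 library left out between 11 and 16 lists passed, of which between 8 and 13 were among the 14. For cholesterol synthesis the adjusted p was 0.813, 0.585 and 0.888 with the estimated correlation, with fry, and with the block and an estimated correlation. It ranged from 7.42e-22 to 0.0538 with 1 library left out. The direction of the exocrine pancreas test turned without control replicate 3 (0.741), where the list median stayed positive at 0.36, and without atorvastatin replicate 3 (0.735), where it was -1.34, and its adjusted p ranged from 5.46e-05 to 0.741 with 1 library left out. The 20 ER stress genes adjusted over the list alone were between 14 and 25 with 1 library left out. The 17 glucose genes became 10 with library size alone and were between 11 and 16 with 1 library left out. The cause of these changes was not tested.

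Replicate numbers did not pair the libraries: the correlations of deviations between same-numbered libraries were -0.031, 0 and -0.048. With the replicate block edgeR called 0 genes, with 2807 at an unadjusted p under 0.05, and 11 lists passed. The adjusted p was 0.0698 for the non-sterol branches, 0.0867 for xenobiotic metabolism, 0.0698 for urea cycle and nitrogen and 0.0844 for exocrine pancreas.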

Other observations

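The 6 lists of this part and their tests were chosen after the data were seen, as were the tests by splits of the libraries, by library size alone, of the genotype, of the unique reads, of the hepatocyte list and of the globin slope by its spread within groups and with 1 library left out; the tests of globin slope and of transcript length were set before their results were seen. In these lists, which share sqstm1 with the list of oxidative and heat stress, autophagy genes had 46 positive and 19 negative fold changes, and an adjusted p of 0.0719 over the 6 lists with an estimated correlation. Their median log2 fold change of 0.47 became -0.05 with library size alone, where it lay 0.48 above the median of all tested genes. Of 65 tested, 13 rose and 1 fell adjusted over the list alone, led by map1lc3a.S, gabarapl2.S and gabarapl2.L, which had 6.64 ± 1.18 CPM in controls and 28.0 ± 5.63 CPM in exposed liver (SD, n = 3; log2 fold change 2.08, SE 0.27). The list of cytosolic aminoacyl-tRNA synthetases, below called synthetase genes, also holds the accessory genes aimp1, aimp2 and eef1e1 of the synthetase complex. Of its 37 genes, 18 fell and 0 rose adjusted over the list alone (camera adjusted p = 0.134 with an estimated correlation). The exposed libraries lay entirely above the controls in 5, namely aimp1.S, qars1.S, qars1.L, kars1.L and gars1.S. The 18 that fell included vars1.S and aars1.L (97.5 ± 18.0 to 31.1 ± 2.58 CPM, log2 fold change -1.65, SE 0.26). In serine and one-carbon metabolism (adjusted p = 0.0635 with an estimated correlation) 8 of 19 fell, including all 3 steps of serine synthesis: phgdh.L (8.63 ± 2.07 to 0.314 ± 0.299 CPM, -4.80, SE 0.68), psat1.S (-3.36, SE 0.64) and psph.L (-2.82, SE 0.41). In ER glycosylation and translocation 16 of 58 fell, in the proteasome 3 of 66, and in the cytosolic chaperonin 6 of 23 fell and 2 rose.

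These groups may form a coordinated difference in protein and amino acid metabolism between the livers, a hypothesis from these data. Members outside the 60 genes of smallest p were counted where the groups separated in the direction of the list: 22 autophagy genes of 60 against at most 7 in any other split of the libraries, 22 synthetase genes of 35 against 2, 6 serine and one-carbon genes of 17 against 3, 24 ER glycosylation genes of 57 against 10, 32 proteasome genes of 66 against 20, and 8 chaperonin genes of 23 against 3. Separation was also more frequent over all tested genes in the real split, at 22.7% against 5.9 to 12.2% in the others and 10% by chance. With an estimated correlation no list passed adjusted over the 6 (p = 0.024, 0.0668, 0.0106, 0.129, 0.223 and 0.379 in the order just given; the lowest adjusted p was 0.0635), so that the hypothesis stays open. No record of feeding or stage per library was used here.

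The 10 splits of the 6 libraries are too few for a share under 0.05. Each count of splits as large or as small given here includes the real split. The real split gave 12 genes and the highest other 3, with 1 split as large; 14 lists against 19, with 4 splits as large; 20 ER stress genes against 2, and 17 glucose genes against 0, with 1 split as large in each. For cholesterol synthesis, 5 splits gave a camera p as small as the real one, the smallest being 8.46e-39. For the ER stress list the real camera p was 1.79e-17, and 2 splits gave one as small, the other being control replicates 1 and 2 with atorvastatin replicate 3 against the rest, at 3.89e-19.

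The 10 genes that rose were weighed against RNA of red blood cells, since globin reads were more abundant in exposed liver. Within groups their log2 CPM had a median slope of 0.06 on the log2 globin share, with an upper quartile of 0.12 (0.11 to 0.24 with 1 library left out). Globin genes had a median slope of 1.44, but they make up this share, so their slope is no independent benchmark. The log2 globin share had an SD of 0.6 within groups and the 10 genes that rose a median SD of 0.22. Within groups these genes as a set thus did not follow the globin share, although lyar.L, with a slope of 0.12 (SE 1.08), is not decided. Small positive slopes beyond their SE were found for tmem86a.L (0.29, SE 0.06) and LOC121397773 (0.12, SE 0.05). The lower quartile of the slopes was -0.16. With 1 library left out the highest single slope was 0.83, without atorvastatin replicate 3. The genes were called in part for a small spread within groups, at a median percentile of 15.8. Tested genes with a mean of at least 1 CPM had a median SD of 0.39. A small spread itself limits the slope, so the slope alone cannot exclude red cell RNA as their source. Globin took 6.15 and 5.62% of reads in control replicates 2 and 3, and 8.29 and 8.12% in atorvastatin replicates 1 and 3. In these libraries gabarapl2.S, of smallest fold change among the 10, had 6.65 and 5.50 against 22.75 and 19.0 CPM. LOC121397773 had 200.5 and 188.1 against 1374 and 1257 CPM. These values, picked after the data were seen, argue against the amount of red cell RNA as sole source. The change from TMM factors to library size alone moved the median of all tested genes from -0.025 to -0.531. The 10 genes had log2 fold changes of 1.86 or more, so that they kept their direction was assured. All 10 also kept their call. The choice between these scalings thus does not account for the rises. An effect of the exposure, a change within the red cells, and any other difference between the groups stay open.

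For the lower ER stress list, dilution of liver RNA by red cells would lower hepatocyte genes alike. But the median of the hepatocyte list lay 1.3 above that of the ER list on the log2 scale. The lower bootstrap bound of 1.01 came from resampling genes within each list. It leaves out the spread between libraries and the correlation between genes, and is therefore too narrow. Transcript length and expression level are also argued against: the ER median of -0.71 lay outside the middle 95% of 10000 matched lists, which ran from -0.17 to 0.27. Exposure, feeding and stage remain open and were not tested.

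For LOC108699348, reads moved to a near-identical copy are argued against, as 100% of its control reads were unique to a transcript. A genotype difference between animals is a candidate explanation: other splits of the libraries gave up to 3 genes with at least 1 CPM on one side and under 0.05 CPM on the other, among them xdh.S, against 1 in the real split. An effect of exposure on this gene stays open.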
